A study of Homo sapiens with 54 samples.

How the data were processed

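Gene expression was measured in 54 cultures of HepG2 cells on single-channel arrays. Per the labels' protocols, cells were grown in 6-well plates, exposed before full confluence to a compound or to 0.5 percent DMSO, lysed in Trizol, and total RNA was labelled as biotinylated cRNA by the standard Affymetrix procedure. The deposited table holds log2 expression values made by the authors with RMA, per the submitters' processing notes. RMA corrects the background, normalizes between arrays and summarises probes, so differences in total RNA per cell cannot be seen in its values. Its version and the probe set definition are not given in the sources used here. The row names are Ensembl gene IDs with a suffix, which points to probe sets redefined per gene. The table had 20056 rows and 54 columns with 0 missing values, array medians between 5.70 and 6.21, and values between 2.46 and 14.8. No 2 arrays were identical, with a highest correlation of 0.997.

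Samples were grouped by the compound and time in the labels, with 3 biological replicates per compound and time. The 6 DMSO arrays of a time were 1 group. The labels name, for every compound array, the 2 DMSO arrays of the same time and number as its matching controls, so the replicate number within a time was a fixed block. Deviations from group means had a mean correlation across genes of 0.242 at 24 h and 0.205 at 48 h between arrays of the same number. Between arrays of different numbers it was -0.112 and -0.101. As deviations cancel within a group, these negative values follow from the positive ones and add no evidence. Of 105 pairs with the same number at each time, 76 and 73 were above 0.1, so the block rests on the labels and not on every pair.

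Values were analysed as deposited, with no filter, in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided). All 54 arrays entered 1 fit with 16 groups and the block, with 34 residual degrees of freedom, so that all groups shared an estimate of the spread. Genes were called at an adjusted p under 0.05 after Benjamini-Hochberg adjustment within each contrast. The contrasts were each compound minus DMSO at each time, the difference between times for each compound, and averages over compounds of a class. The DMSO exposures were compared in a fit with 18 groups, and DMSO at 48 h was compared with 24 h after averaging the 2 exposures of a number, without a block. Which compound belongs to which class is not in the labels and was taken from general knowledge.

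The rule for named genes, fixed before the data were examined, took the largest rises and falls among called genes. For a compound against DMSO, all 3 replicates also had to move the same way against their matched DMSO arrays. This check was not applied to IDs named for the time differences, the class comparisons or DMSO between times. Of the 20056 IDs, 0 matched a symbol in the reference table, whose Ensembl column was empty. The part of the rule that names genes by symbol and the tests of the fixed gene lists were therefore not run, and the number of IDs per comparison was reduced to 2 that rose and 2 that fell. Fold changes are 2 to the power of the fitted log2 difference.

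The method was tested on simulated arrays with the real gene means, block effects and residual spread and independent errors between genes, with 200 genes changed among 20056. Of genes changed by 1 on the log2 scale, 94.0 percent were recovered for 2-nitrofluorene at 24 h, 83.6 percent for NNK at 24 h and 86.6 percent for NNK at 48 h. For a log2 change of 0.585, the values were 50.8, 43.3 and 49.3 percent. For the DMSO comparison between times, 58.2 percent were recovered at a log2 change of 1. For these 4 comparisons, 6, 19, 9 and 8 of the 19856 unchanged genes were called.

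Alternatives fixed before the data were examined were no replicate block, only the compound and its DMSO arrays in the fit, DMSO exposures averaged or used singly, rows with the lowest mean values (a share of 0.25) left out, arrays centred on the median, cyclic loess, eBayes with trend and robust options, and each replicate left out. Chosen after seeing the data were leaving out the 4 arrays with a slope under 0.95 on the mean of all arrays, each of these alone, each of the 54 arrays alone, and array weights (limma arrayWeights), whose iteration stopped before its convergence tolerance was met. Scan dates and hybridisation batches are not given in the sources used here, so no batch other than the replicate number was tested.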

Results

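Gene expression was measured in HepG2 cells, a human hepatocellular carcinoma cell line widely used as a liver cell model in toxicology. Cultures were exposed for 24 h or 48 h to 1 of 7 compounds or to the solvent, dimethyl sulfoxide (DMSO), at 0.5 percent. The compounds were 2-nitrofluorene at 35 µM, NNK (nicotine-derived nitrosamine ketone) at 10 mM, methapyrilene hydrochloride at 114 µM, piperonyl butoxide at 45 µM, clonidine at 95 µM, nifedipine at 420 µM and tolbutamide at 2.1 mM. Each compound and time had 3 biological replicates, and each time had 6 DMSO arrays from 2 solvent exposures of 3 replicates, which gave 54 arrays in 16 groups. The design describes 2 genotoxic carcinogens, 2 non-genotoxic carcinogens and 3 compounds that are neither. From general knowledge, 2-nitrofluorene and NNK were taken as the first class, methapyrilene and piperonyl butoxide as the second, and clonidine, nifedipine and tolbutamide as the third. Each array gave a log2 expression value for 20056 Ensembl gene IDs. The files do not pair these IDs with gene names, so genes are given by ID, with at most 2 that rose and 2 that fell in each comparison. The number of arrays limits the precision of every value.

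The 54 arrays did not have the same spread of values. The slope of each array on the mean of all arrays was between 0.965 and 1.04 in 50 arrays. It was 0.678 in piperonyl butoxide 48 h replicate 1, 0.798 in NNK 24 h replicate 2, 0.858 in piperonyl butoxide 24 h replicate 2 and 0.911 in DMSO 24 h exposure 2 replicate 2. Counts are therefore given with all arrays and, as a comparison chosen after seeing the data, without these 4 low-spread arrays. None of the 4 was an array of 2-nitrofluorene, methapyrilene, clonidine, nifedipine or tolbutamide, or a 48 h DMSO array. For these compounds at 48 h the log2 changes were the same in both settings. Their 48 h counts therefore differed through the shared estimate of the spread.

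**Figure D1:**
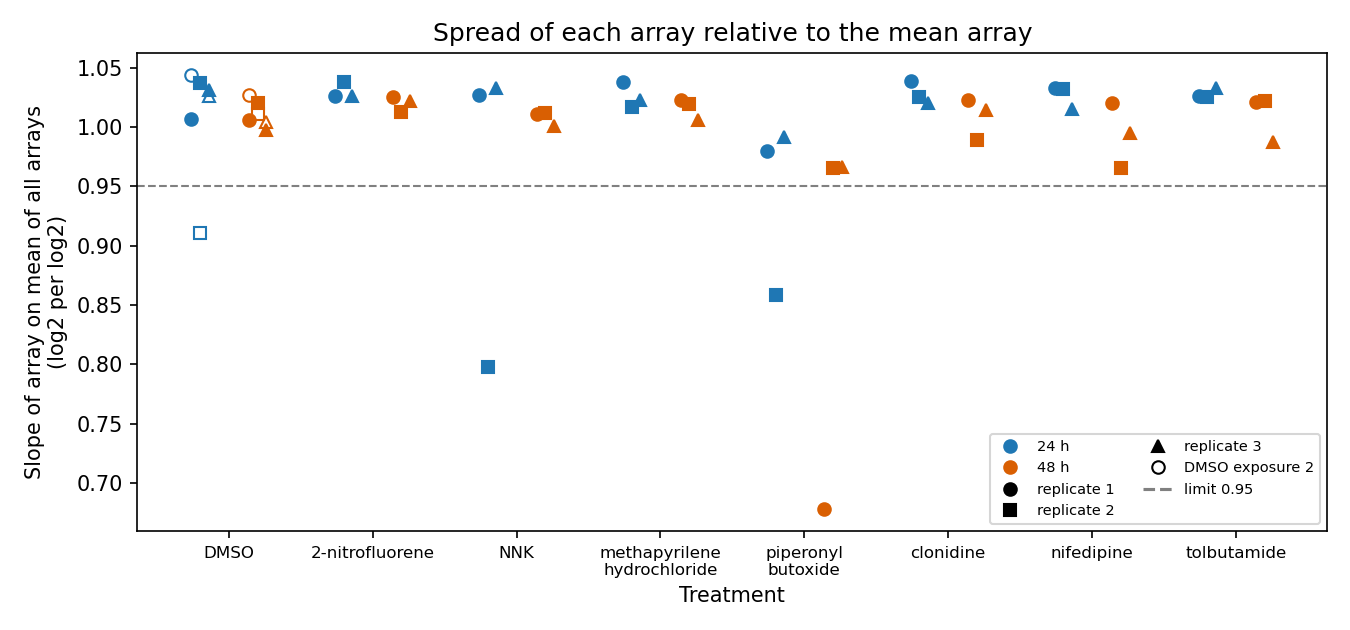
Slope of each array's log2 values on the mean of all 54 arrays (y axis, log2 per log2) by treatment (x axis), coloured by time, with symbols for the replicate number and open symbols for DMSO exposure 2. The 4 arrays under the dashed line at 0.95 lie between 0.678 and 0.911, and the other 50 lie between 0.965 and 1.04.

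The solvent comparison gave the background. Between the 2 DMSO exposures limma called 0 genes at 24 h and 0 at 48 h, with 271 and 1037 genes at an unadjusted p under 0.05. Leaving out the 4 low-spread arrays gave 1 call at 24 h (adjusted p = 0.0465) and 0 at 48 h (smallest adjusted p = 0.152), with 619 and 2754 genes at an unadjusted p under 0.05. By chance a share of 0.05 of the 20056 genes would lie under this p. The 271 lay below that share and the 2754 above it. The 0 calls at 48 h therefore do not show that the 2 exposures were alike. Between 24 h and 48 h of DMSO alone, 5 genes were called, of which 2 rose and 3 fell. ENSG00000070669 rose by 2.41 (SE 0.16, adjusted p = 0.0234) and ENSG00000112818 by 1.26 (SE 0.11, adjusted p = 0.0391) on the log2 scale. ENSG00000112984 fell by 1.36 (SE 0.12, adjusted p = 0.0391) and ENSG00000138778 fell by 1.20 (SE 0.11, adjusted p = 0.0391). This comparison rested on 3 averaged samples per time. The count was 125 (17 rose, 108 fell) without DMSO 24 h exposure 2 replicate 2, and between 0 and 3 without any of 7 other single DMSO arrays.

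2-Nitrofluorene, a nitrated polycyclic aromatic compound, changed a small set of genes, most of them upwards and some by a large factor. ENSG00000140465 went from 5.73 ± 0.39 (SD, n = 6) in DMSO to 9.97 ± 0.83 (SD, n = 3) at 24 h, a rise of 4.24 on the log2 scale (SE 0.22), or 18.9-fold, with adjusted p = 1.02e-16. At 48 h the same ID rose by 3.87 (SE 0.22, adjusted p = 2.29e-15). ENSG00000198074 rose by 3.33 (SE 0.34, adjusted p = 2.58e-08) at 24 h and by 3.40 (SE 0.34, adjusted p = 1.13e-08) at 48 h, near 10.0-fold and 10.6-fold. At 24 h ENSG00000107984 fell by 1.45 (SE 0.30, adjusted p = 0.0118) and ENSG00000125144 fell by 1.10 (SE 0.25, adjusted p = 0.0362). At 48 h ENSG00000125144 fell by 1.76 (SE 0.25, adjusted p = 3.54e-05) and ENSG00000139055 fell by 1.62 (SE 0.17, adjusted p = 6.52e-08). By the rule for named genes, each of these IDs was picked for moving the same way in 3 of 3 replicates against the matched DMSO arrays. In all, 65 genes were called at 24 h (55 rose, 10 fell) and 74 at 48 h (60 rose, 14 fell), and 37 were called in the same direction at both times, where independent lists would share 0.171. The counts were 131 and 222 without the 4 low-spread arrays, with 76.3 and 68.9 percent of them rises, and 35 and 42 without the replicate block. Without its own replicate 1 or 2 the 24 h count was 33 or 26, and without its own replicate 1, 2 or 3 the 48 h count was 42, 38 or 45. It was 117 without piperonyl butoxide 48 h replicate 1.

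NNK, a tobacco-specific nitrosamine, gave 0 called genes at 24 h and 0 at 48 h in limma, with 1431 and 293 genes at an unadjusted p under 0.05. The first lay above and the second below the share of 0.05 of the 20056 genes that chance gives. ENSG00000140465, which rose under 2-nitrofluorene, differed from DMSO by 0.12 (SE 0.22, adjusted p = 0.816) at 24 h and by 0.28 (SE 0.22) at 48 h. No gene was called without the 4 low-spread arrays either, with 568 and 1140 genes at an unadjusted p under 0.05. With array weights 1 gene was called at 48 h. As NNK had no calls, the number of genes called under both 2-nitrofluorene and NNK could only be 0 at each time, so their overlap was not tested.

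Methapyrilene hydrochloride, an antihistamine, changed more genes at 48 h than at 24 h by count. At 24 h ENSG00000151012 rose by 2.56 (SE 0.30, adjusted p = 1.39e-06) and ENSG00000070669 by 2.42 (SE 0.27, adjusted p = 5.69e-07), which is 5.88-fold and 5.33-fold. ENSG00000107984 fell by 1.46 (SE 0.30, adjusted p = 0.00351) and ENSG00000100297 fell by 1.26 (SE 0.16, adjusted p = 4.74e-06). At 48 h ENSG00000163393 went from 4.84 ± 0.30 (SD, n = 6) to 8.01 ± 0.74 (SD, n = 3), a 9.01-fold rise (adjusted p = 4.10e-09), and ENSG00000078081 rose 6.66-fold (adjusted p = 2.27e-13). ENSG00000107984 fell by 2.43 (SE 0.30, adjusted p = 3.68e-07) and ENSG00000152253 fell by 2.37 (SE 0.33, adjusted p = 3.88e-06). The calls numbered 307 at 24 h (125 rose, 182 fell) and 1002 at 48 h (473 rose, 529 fell), with 227 shared in the same direction against 7.75 for independent lists. Rises outnumbered falls at 48 h after centring each array (431 and 403), after cyclic loess (656 and 553) and without the 4 low-spread arrays (1290 and 1204), among other settings. The counts were 772 and 2494 without the 4 low-spread arrays and 164 and 632 without the replicate block. The 24 h count was 474 without piperonyl butoxide 48 h replicate 1 alone. Without methapyrilene replicate 1, 2 or 3 the counts were 129, 168 and 168 at 24 h and 650, 560 and 629 at 48 h. At 48 h the log2 change of ENSG00000107984 stayed -2.43 without the 4 low-spread arrays, while its SE went from 0.30 to 0.15.

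Piperonyl butoxide, an insecticide synergist that inhibits cytochrome P450 enzymes, gave the highest counts of the 7 compounds. At 24 h ENSG00000109321 went from 6.89 ± 0.81 (SD, n = 6) to 12.5 ± 0.19 (SD, n = 3), a 50.1-fold rise (adjusted p = 4.05e-13), and ENSG00000169429 rose 29.7-fold (adjusted p = 1.09e-18). ENSG00000059804 fell by 4.10 (SE 0.41, adjusted p = 2.10e-10) and ENSG00000101003 fell by 3.61 (SE 0.37, adjusted p = 3.98e-10). At 48 h ENSG00000109321 rose 40.4-fold (adjusted p = 7.15e-13) and ENSG00000140465 rose 32.1-fold (adjusted p = 3.97e-20). ENSG00000059804 fell by 4.97 (SE 0.41, adjusted p = 7.92e-13) and ENSG00000146038 fell by 4.85 (SE 0.46, adjusted p = 4.99e-11). Without the 4 low-spread arrays the 48 h log2 change was 6.26 for ENSG00000109321, against 5.34 with all arrays, and -4.03 for ENSG00000146038. At 24 h 5208 genes were called (2183 rose, 3025 fell) and at 48 h 11780 (7648 rose, 4132 fell), and 4318 were shared in the same direction against 1456 for independent lists. The excess of falls at 24 h turned with array weights (6823 rose, 4888 fell). The 48 h direction of the set depended on scaling and on 1 array. The median change of all genes at 48 h was 0.21, and it was 0.080 after centring each array and 0.014 after cyclic loess, and the share of calls that rose was 64.9, 55.3 and 48.4 percent respectively. Without piperonyl butoxide 48 h replicate 1 the 48 h count was 5900, and without the 4 low-spread arrays it was 7730 (3936 rose, 3794 fell).

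Clonidine, an alpha adrenergic agonist, gave 1 call at 24 h and 77 at 48 h. ENSG00000109205 rose by 1.52 (SE 0.22, adjusted p = 0.000473) at 24 h. At 48 h ENSG00000112337 went from 7.49 ± 0.39 (SD, n = 6) to 9.57 ± 0.39 (SD, n = 3), a 4.24-fold rise (adjusted p = 1.55e-06), and ENSG00000118520 rose 2.96-fold (adjusted p = 0.0129). ENSG00000109321, which rose most under piperonyl butoxide, fell by 1.81 (SE 0.43, adjusted p = 0.0447), and ENSG00000167552 fell by 1.47 (SE 0.35, adjusted p = 0.0415). Of the 77 genes 54 rose and 23 fell, and the share that rose was 70.1 percent, against 82.3 percent after centring each array and 60.2 percent (207 rose, 137 fell) without the 4 low-spread arrays. The counts were 3 and 344 without the 4 low-spread arrays, and 0 and 21 without the replicate block. Without its own replicate 1, 2 or 3 the 48 h count was 38, 20 or 25, and without piperonyl butoxide 48 h replicate 1 it was 125. The 24 h count was 2 or 3 when any of 6 single arrays was left out, among them its own replicate 3.

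Nifedipine, a calcium channel blocker, changed genes at both times. At 24 h ENSG00000151012 rose 9.48-fold (adjusted p = 1.03e-09) and ENSG00000070669 rose 9.12-fold, from 9.25 ± 0.27 (SD, n = 6) to 12.4 ± 0.22 (SD, n = 3), with adjusted p = 1.52e-10. ENSG00000107984 fell by 2.43 (SE 0.30, adjusted p = 2.81e-07) and ENSG00000112984 fell by 2.15 (SE 0.15, adjusted p = 1.79e-12). At 48 h ENSG00000121552 rose 6.95-fold (adjusted p = 4.66e-08) and ENSG00000160712 rose 4.46-fold (adjusted p = 2.39e-06). ENSG00000059804 fell by 3.42 (SE 0.41, adjusted p = 1.38e-07) and ENSG00000170525 fell by 3.13 (SE 0.44, adjusted p = 3.38e-06). The calls numbered 1641 at 24 h (708 rose, 933 fell) and 1162 at 48 h (492 rose, 670 fell), with 604 shared in the same direction against 48.5 for independent lists. The excess of falls at 48 h turned with DMSO exposure 2 alone (560 rose, 548 fell) and with array weights (1678 rose, 1604 fell). They were 2894 and 2786 without the 4 low-spread arrays, and 1089 and 771 without the replicate block. Without its own replicate 1 or 2 the 24 h count was 744 or 805, and without its own replicate 2 or 3 the 48 h count was 689 or 710.

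Tolbutamide, a sulfonylurea used to lower blood glucose, changed genes at both times, more of them downwards by count. ENSG00000108932 rose 7.15-fold at 24 h (adjusted p = 0.000792) and 6.11-fold at 48 h (adjusted p = 0.0019). ENSG00000070669 rose 6.26-fold at 24 h (adjusted p = 1.95e-08), and ENSG00000112299 went from 4.52 ± 0.14 (SD, n = 6) to 6.91 ± 0.13 (SD, n = 3) at 48 h, a 5.23-fold rise (adjusted p = 3.80e-08). ENSG00000107984 fell by 1.85 (SE 0.30, adjusted p = 0.000127) at 24 h and by 1.99 (SE 0.30, adjusted p = 3.27e-05) at 48 h. ENSG00000170345 fell by 1.51 (SE 0.38, adjusted p = 0.0222) at 24 h, and ENSG00000139055 was lower at 48 h with adjusted p = 1.12e-09. The calls numbered 405 at 24 h (172 rose, 233 fell) and 441 at 48 h (120 rose, 321 fell), with 213 shared in the same direction against 4.76 for independent lists. At 48 h 27.2 percent of the calls rose, against 37.5 percent after cyclic loess and 37.8 percent without the 4 low-spread arrays. The counts were 1068 and 1167 without the 4 low-spread arrays, 233 and 255 without the replicate block, and 611 at 24 h without piperonyl butoxide 48 h replicate 1. Without its own replicate 1, 2 or 3 they were 202, 198 and 204 at 24 h and 246, 247 and 262 at 48 h.

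**Figure D2:**
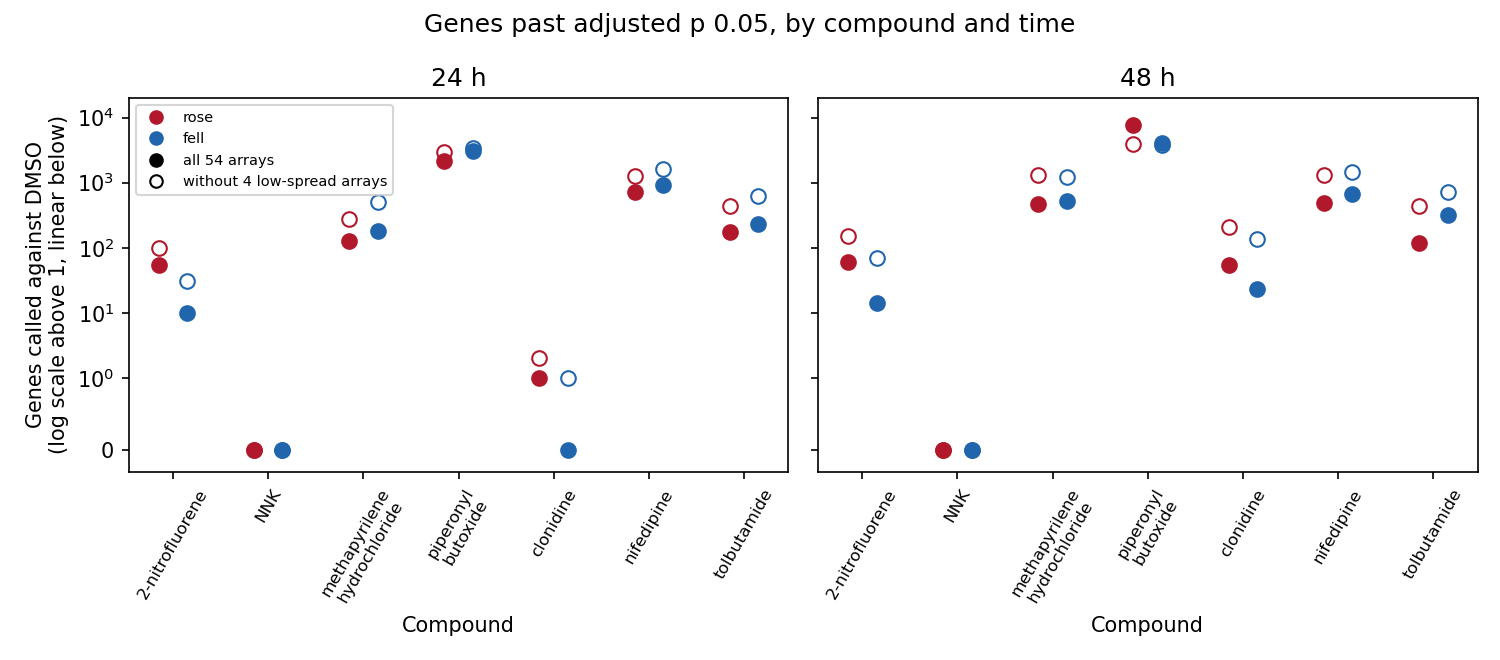
Number of genes past adjusted p 0.05 against DMSO (y axis, log scale above 1) for each compound (x axis) at 24 h and 48 h. Red points rose and blue points fell; filled points use all 54 arrays and open points leave out the 4 low-spread arrays. NNK has 0 at both times, and piperonyl butoxide at 48 h goes from 7648 rises and 4132 falls to 3936 and 3794.

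The change between 24 h and 48 h was tested directly, as the 48 h change minus the 24 h change. Under methapyrilene ENSG00000078081 had the larger rise at 48 h, by 2.71 (adjusted p = 1.33e-08), and ENSG00000139055 was lower by a difference of -1.33 (adjusted p = 0.0072). Under piperonyl butoxide ENSG00000151012 differed by -3.30 (adjusted p = 1.66e-05) and ENSG00000139269 by -2.99 (adjusted p = 2.53e-07), and ENSG00000132002 differed by 1.65 (adjusted p = 0.000831). These differences were -2.68 for ENSG00000151012 and 2.35 for ENSG00000132002 without the 4 low-spread arrays. ENSG00000070669 differed by -2.11 (adjusted p = 0.00607) under nifedipine and by -2.56 (adjusted p = 0.000759) under tolbutamide, as its rise at 24 h was not matched at 48 h, and the same ID rose in DMSO alone between the times. Under clonidine ENSG00000109193 differed by 1.25 (adjusted p = 0.00111). The counts were 18 for methapyrilene, 214 for piperonyl butoxide, 1 for clonidine, 8 for nifedipine and 6 for tolbutamide. They were 0 in limma for 2-nitrofluorene and 0 for NNK, with 141 and 603 genes at an unadjusted p under 0.05. Both values lay below the share of 0.05 of the 20056 genes that chance gives. Without the 4 low-spread arrays the counts of called genes were 112 for methapyrilene, 391 for piperonyl butoxide, 48 for nifedipine and 12 for tolbutamide. Single arrays moved these counts by over 1.5 times. Methapyrilene gave 5, 8 and 6 without its 24 h replicate 1, its 24 h replicate 2 and its 48 h replicate 2. Tolbutamide gave 3, 3 and 2 without its 24 h replicates 1 and 2 and its 48 h replicate 3. Nifedipine gave 5 without its 24 h replicate 1, its 24 h replicate 2 or its 48 h replicate 2, 36 without its 24 h replicate 3 and 13 without DMSO 48 h exposure 1 replicate 3. Piperonyl butoxide gave 784 without its 48 h replicate 2, 625 without its 48 h replicate 3, 98 without its 24 h replicate 3 and 126 without DMSO 24 h exposure 1 replicate 1. Leaving out piperonyl butoxide 48 h replicate 1 gave 19 for nifedipine and 11 for tolbutamide.

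Several IDs recurred across compounds. All compounds of a time were compared with the same DMSO arrays, so these recurrences are not independent. ENSG00000140465 rose under 2-nitrofluorene and piperonyl butoxide at both times, by 3.87 to 5.00 on the log2 scale, and by 0.96 (adjusted p = 0.00333) and 1.49 (adjusted p = 8.52e-06) under nifedipine. It also rose by 0.80 (adjusted p = 0.041, or 0.0131 without the 4 low-spread arrays) under tolbutamide at 48 h. ENSG00000070669 rose at 24 h under 2-nitrofluorene by 1.53 (adjusted p = 0.00121), and under methapyrilene, piperonyl butoxide, nifedipine and tolbutamide by 2.42 to 3.19. ENSG00000107984 fell at both times under 2-nitrofluorene, methapyrilene, nifedipine and tolbutamide, and ENSG00000059804 fell at both times under piperonyl butoxide and nifedipine, and at 48 h under methapyrilene by 1.71 (adjusted p = 0.0058) and tolbutamide by 1.48 (adjusted p = 0.0389).

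**Figure D3:**
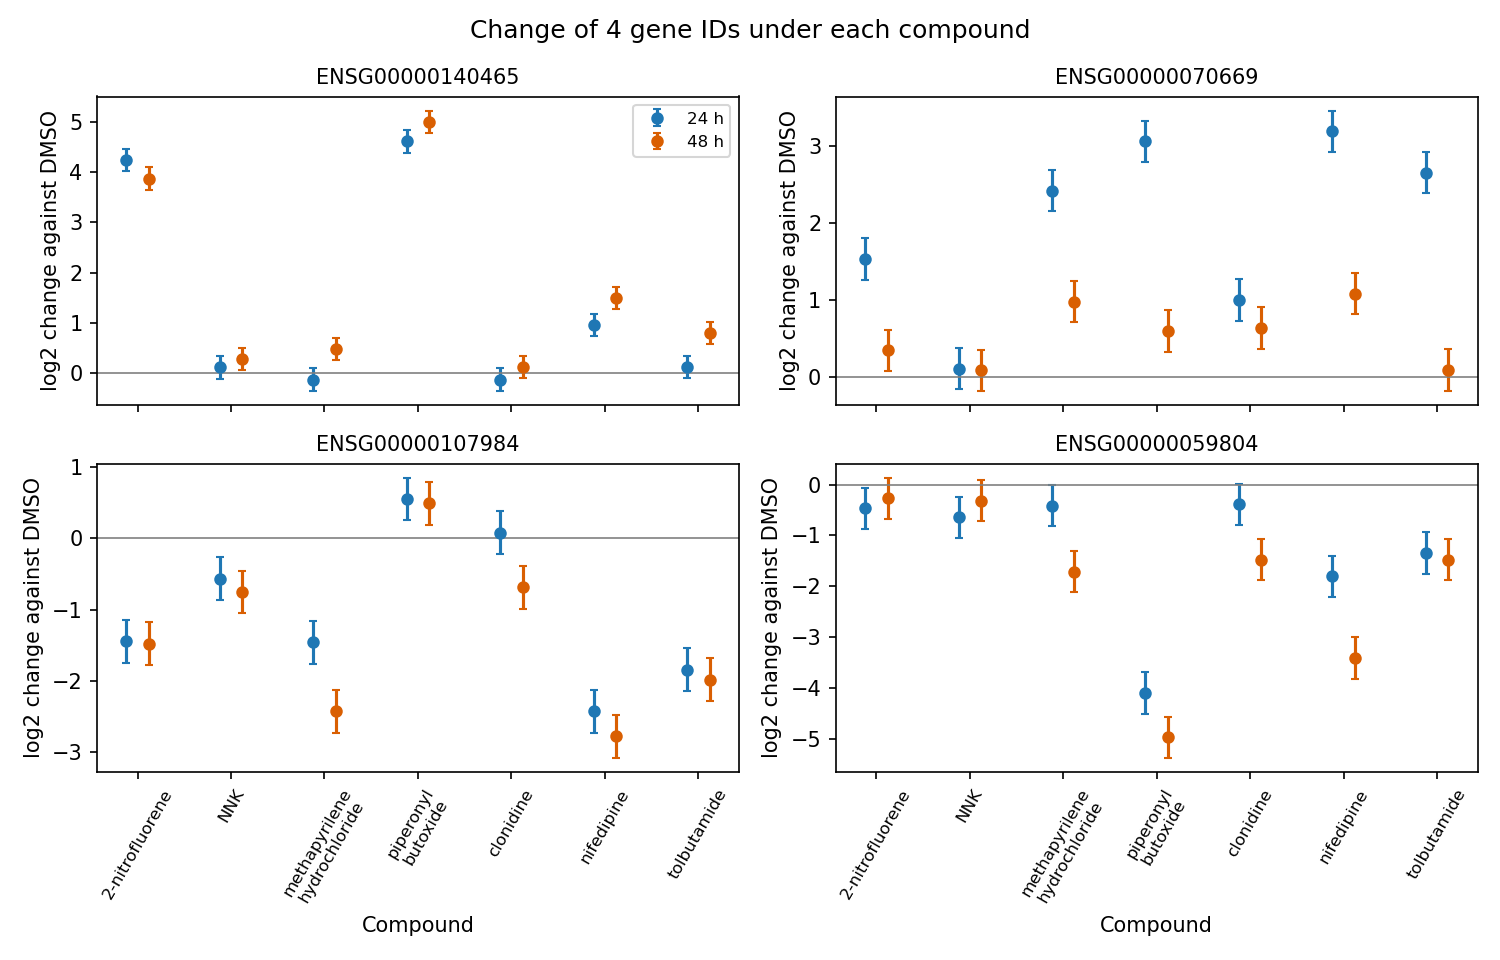
Change against DMSO (y axis, log2) of 4 gene IDs under each compound (x axis) at 24 h and 48 h, with bars of 1 SE of the fit. ENSG00000070669 lies at 2.42 to 3.19 at 24 h in methapyrilene, piperonyl butoxide, nifedipine and tolbutamide and at 1.08 or less in every compound at 48 h.

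The compounds were compared for shared calls in 21 pairs, of which the 6 with NNK could share only 0. The 3 pairs given first were chosen after their values were seen. Methapyrilene and nifedipine shared 228 calls in the same direction at 24 h and 516 at 48 h, where independent lists would share 12.9 and 29.3. Methapyrilene and tolbutamide shared 157 and 268, against 3.19 and 11.3. Nifedipine and tolbutamide shared 285 and 272, against 16.9 and 13.7. In the same order, these numbers without the 4 low-spread arrays were 547 and 1131 against 57.5 and 173, 430 and 660 against 21.6 and 72.0, and 665 and 639 against 78.6 and 82.0. As all compounds use the same DMSO arrays, the comparison was repeated with 1 DMSO exposure for each compound. The 3 pairs then shared 118 to 132, 80 to 86 and 134 to 158 calls at 24 h, where independent lists would share 4.11 to 5.22, 0.847 to 1.14 and 4.50 to 7.70. At 48 h they shared 300 to 322, 142 to 166 and 145 to 171, against 9.83 to 27.8, 5.92 to 7.03 and 4.29 to 13.7. The covariance of the 24 h changes across genes was 0.0543 for methapyrilene and nifedipine, against 0.0125 in simulated unchanged groups. The correlation was 0.703 with pooled and 0.545 with split controls. Genes are not independent replicates. The simulation had independent genes and gave a gene the same spread in every array, so its covariances are only a rough reference. At 24 h NNK and clonidine, with almost no calls, had a covariance of -0.0143 against a simulated 0.0133. At 48 h the split correlation of methapyrilene and tolbutamide was 0.407 or 0.433, by which exposure each compound was given. It depended more on the exposure for methapyrilene and nifedipine (0.205 or 0.662) and for nifedipine and tolbutamide (0.582 or 0.110). The 5 pairs of piperonyl butoxide with these and the other compounds had smaller ratios of shared calls to those of independent lists. The length of the piperonyl butoxide lists, 5208 and 11780 calls, caps this ratio, so it does not show weaker sharing. The 48 h covariance of piperonyl butoxide with nifedipine was 0.118, against 0.0127 in simulated unchanged groups, and the split correlation was 0.494 or 0.379. Piperonyl butoxide shared 209 and 585 calls with methapyrilene against 41.1 and 289, 888 and 784 with nifedipine against 218 and 326, and 261 and 247 with tolbutamide against 53.9 and 112. At 48 h it shared 29 with clonidine against 25.3 and 38 with 2-nitrofluorene against 25.8. Without the 4 low-spread arrays these 48 h values were 141 against 66.5 and 129 against 43.1. The 48 h covariance of piperonyl butoxide with tolbutamide was 0.00541, below the 0.0127 of simulated unchanged groups. Without the 4 low-spread arrays it was 0.0166, above the simulated 0.00546. The remaining 7 pairs, of 2-nitrofluorene or clonidine, shared 0 to 29 calls at 24 h and 10 to 49 at 48 h, with the highest in 2-nitrofluorene and nifedipine (against 2.41) and in methapyrilene and clonidine (against 1.88).

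The class comparisons averaged the named compounds and speak of these compounds only. For 2-nitrofluorene and NNK minus the other compounds, 1009 genes were called at 24 h (630 higher, 379 lower) and 1767 at 48 h (1277 higher, 490 lower). The 48 h split was 1004 higher and 781 lower after cyclic loess, and 2149 and 1429 without the 4 low-spread arrays. At 24 h ENSG00000243955 was higher by 1.56 (adjusted p = 1.08e-05) and ENSG00000070669 lower by a difference of -1.65 (adjusted p = 6.83e-08). At 48 h ENSG00000059804 was higher by 2.32 (adjusted p = 1.28e-07) and ENSG00000163393 lower by a difference of -1.91 (adjusted p = 4.36e-08). Against DMSO, ENSG00000059804 changed by -0.27 under 2-nitrofluorene and -0.31 under NNK, neither past the threshold, and by -4.97 under piperonyl butoxide and -3.42 under nifedipine. ENSG00000163393 changed by 0.14 and -0.17 under the first pair, not past the threshold, and rose by 3.17 under methapyrilene and 3.35 under piperonyl butoxide. Over all genes, called or not, both of the first compounds lay on 1 side of all the others in 6.01 percent at 24 h and 8.66 percent at 48 h, below the 9.52 percent that a random choice of 2 compounds gives, and in 10.2 and 9.84 percent without the 4 low-spread arrays. For methapyrilene and piperonyl butoxide minus clonidine, nifedipine and tolbutamide, 2642 genes were called at 24 h (958 higher, 1684 lower) and 4076 at 48 h (1879 higher, 2197 lower). Of these, 35 and 243 were called against DMSO under both compounds and lay outside the values of the other 3, or 119 and 632 without the 4 low-spread arrays. ENSG00000143632 was higher by 2.75 (adjusted p = 2.23e-15) and 3.11 (adjusted p = 2.30e-17). ENSG00000250337 was lower at 24 h by a difference of -1.87 (adjusted p = 0.00067) and ENSG00000171560 at 48 h by -2.07 (adjusted p = 3.55e-13). Against DMSO these 3 IDs were past the threshold under piperonyl butoxide and not under methapyrilene. ENSG00000143632 changed by 4.80 and 4.85 under the former and by -0.47 and -0.66 under the latter, ENSG00000250337 at 24 h by -2.83 and 0.69, and ENSG00000171560 at 48 h by -3.55 and -0.43. Over all genes, both compounds lay on 1 side of the other 3 in 18.5 percent at 24 h and 13.7 percent at 48 h. A random choice gives 20 percent, and without the 4 low-spread arrays the values were 18.4 and 18.7 percent. Array weights turned the direction of the 24 h calls of this comparison, to 4120 higher and 3713 lower. The first comparison gave 2108 and 3578 genes without the 4 low-spread arrays and 638 and 1136 without the replicate block. Its 24 h count was 631 without 2-nitrofluorene 24 h replicate 1 and 1612 without piperonyl butoxide 48 h replicate 1.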

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

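The tests on the piperonyl butoxide count and on NNK without the low-spread arrays were chosen after the results were seen.

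Among the 6 DMSO arrays of 24 h, exposure 2 replicate 2 stood apart in its slope on the mean of all arrays, 0.911 against 1.01 to 1.04 in the others, a gap of 0.720 of the range. It was also lowest for ENSG00000107984, at 8.01 against 9.33 to 9.84 (gap 0.723), and for ENSG00000196177, at 8.14 against 9.55 to 10.3 (gap 0.659). DMSO 24 h exposure 1 replicate 1 was highest for ENSG00000140465, at 6.49 against 5.33 to 5.68 (gap 0.703). At 48 h exposure 1 replicate 2 was highest for ENSG00000169429 (gap 0.652), exposure 2 replicate 2 for ENSG00000059804 (gap 0.640) and exposure 1 replicate 1 for ENSG00000163393 (gap 0.639). Of 90 sets of 6 DMSO values, 7 were past Dixon's limit for 6 values, and chance gives about 5 percent.

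By the test of the difference between 48 h and 24 h, 18 genes were called under methapyrilene, 214 under piperonyl butoxide, 1 under clonidine, 8 under nifedipine and 6 under tolbutamide. With a replicate number left out the counts were 2 to 5, 35 to 676, 0, 0 to 5 and 0 to 2 in the same order. The splits below are too few for a statement on chance for these counts.

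Piperonyl butoxide gave 11780 calls at 48 h, of which 64.9 percent rose, and 1 of its 3 arrays had the lowest slope of all, 0.678. Without that array 5900 genes were still called and 46.6 percent of them rose, so it is not the whole source of the calls, while the excess of rises is consistent with its compressed range. A low slope brings low genes up and high genes down, and the correlation of change with level across genes was -0.435 at 48 h and -0.297 at 24 h with all arrays, and -0.173 and -0.217 without the 4 low-spread arrays, so part of it remained. In the other 50 arrays 7730 genes were called at 48 h and 6333 at 24 h, with 4769 shared in the same direction against 1219 for independent lists. With all arrays, 1 of 84 splits reached the 48 h count and 2 of 84 the 24 h count, the real split included. The other 24 h split had 5514 calls against 5208. In splits with 1 array of each replicate number the highest other counts were 3261 at 24 h and 7634 at 48 h. The piperonyl butoxide slopes in the 50 arrays were 0.9798 and 0.9915 at 24 h and 0.9656 and 0.9662 at 48 h, against 0.998 to 1.04 in DMSO. A milder difference in spread therefore remained there. The counts argue against the 4 low-spread arrays as the source of the calls as a whole. The splits argue against chance with all arrays, and they were not repeated in the 50 arrays. A response to piperonyl butoxide stays a hypothesis for the calls, while the cause of the remaining dependence on level was not tested.

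NNK gave 0 calls at both times, and 1 of its 24 h arrays had a slope of 0.798. Without the 4 low-spread arrays the count was still 0, which argues against that array hiding changes that the others show. In simulated arrays with the real spread and independent genes, at least 83.6 percent of genes changed by 1 on the log2 scale were called. The simulation gave a gene the same spread in every array, so it does not represent the 24 h array with a slope of 0.798. Recovery with only the remaining NNK 24 h arrays was not simulated. Changes of that size in many genes would therefore have been seen at 48 h, while for 24 h this is not settled. Smaller changes, or changes in few genes, stay open, and array weights gave 1 call at 48 h. Whether the dose or the metabolic capacity of HepG2 cells limits the response was not tested.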

How the results depend on the processing

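Leaving out the low-spread arrays, alone or together, leaving out single arrays, and array weights were chosen after seeing the data. In the comparison it was picked for, no named ID changed direction under the settings that were run for it. These did not include leaving out each of the other 50 arrays alone. The statement does not cover the values of an ID under other compounds or times. Of the comparisons with a named ID, 80 of 80 stayed past the threshold without the 4 low-spread arrays, 76 of 76 with array weights, 76 of 80 with cyclic loess, 72 of 80 with centred arrays, 65 of 76 without the block and 60 to 62 of 80 when a replicate number was left out. It was 44 of 60 with DMSO exposure 1 alone, 47 of 60 with exposure 2 alone, 48 of 60 with averaged exposures and 40 of 45 with only the compound and its DMSO arrays. Counts below are numbers of called genes, and unless the setting itself removes arrays or rows the cause was not tested. The tests of the fixed gene lists and of genes named by symbol were not run, as the IDs are not paired with names. Signal over background is not given in the sources used here, so its limit on weak genes was not assessed. NNK stayed at 0 calls at both times under every setting run but array weights, which fixes its overlap with 2-nitrofluorene at 0 there; the overlap was not computed with array weights.

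Without the replicate block, the 24 h counts were 35 for 2-nitrofluorene, 164 for methapyrilene, 0 for clonidine, 1089 for nifedipine and 233 for tolbutamide, and the 48 h counts were 42, 632, 21, 771 and 255. The time differences were 5 for methapyrilene and 74 for piperonyl butoxide, and the genotoxic contrast gave 638 and 1136. The block moved no other count by more than 1.5 times.

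With only the compound and its DMSO arrays in the fit, which leaves fewer arrays to estimate the spread, the counts were 15 for 2-nitrofluorene, 90 for methapyrilene, 0 for clonidine, 613 for nifedipine and 138 for tolbutamide at 24 h, and 4126 for piperonyl butoxide at 48 h. With the DMSO exposures averaged they were 32, 158, 1084 and 214 for 2-nitrofluorene, methapyrilene, nifedipine and tolbutamide at 24 h. At 48 h they were 45, 667, 32 and 256 for 2-nitrofluorene, methapyrilene, clonidine and tolbutamide. The time differences were then 4, 52, 0 and 3 for methapyrilene, piperonyl butoxide, clonidine and tolbutamide.

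With DMSO exposure 1 alone the 24 h counts were 26, 153, 0, 906 and 231 for 2-nitrofluorene, methapyrilene, clonidine, nifedipine and tolbutamide. At 48 h they were 45, 7831, 36 and 645 for 2-nitrofluorene, piperonyl butoxide, clonidine and nifedipine. Time differences were 4, 29, 0, 0 and 2 for methapyrilene, piperonyl butoxide, clonidine, nifedipine and tolbutamide. With DMSO exposure 2 alone the 24 h counts were 40, 152, 1089 and 177 for 2-nitrofluorene, methapyrilene, nifedipine and tolbutamide. At 48 h they were 559, 46 and 212 for methapyrilene, clonidine and tolbutamide, and time differences were 8, 124, 21 and 0 for methapyrilene, piperonyl butoxide, nifedipine and tolbutamide.

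Leaving out the rows with the lowest mean values (a share of 0.25) gave 0 for the clonidine time difference and 8 for DMSO 48 h minus 24 h. Centred arrays gave 39 for 2-nitrofluorene at 24 h and 3 for DMSO 48 h minus 24 h. Cyclic loess gave 7 and 140 for clonidine, 349 for the piperonyl butoxide time difference and 11 for DMSO 48 h minus 24 h. The trend and robust options gave 3 for the last.

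Without the 4 low-spread arrays the 24 h counts were 131, 772, 3, 2894 and 1068 for 2-nitrofluorene, methapyrilene, clonidine, nifedipine and tolbutamide. At 48 h they were 222, 2494, 7730, 344, 2786 and 1167 for 2-nitrofluorene, methapyrilene, piperonyl butoxide, clonidine, nifedipine and tolbutamide. Time differences were 112, 391, 48 and 12 for methapyrilene, piperonyl butoxide, nifedipine and tolbutamide. The genotoxic contrast gave 2108 and 3578, the DMSO exposures at 24 h gave 1, and DMSO 48 h minus 24 h gave 125, as it did without DMSO 24 h exposure 2 replicate 2 alone. Without piperonyl butoxide 24 h replicate 2 clonidine had 2 calls at 24 h. Without piperonyl butoxide 48 h replicate 1 the counts were 474 and 611 for methapyrilene and tolbutamide at 24 h. They were 117, 5900 and 125 for 2-nitrofluorene, piperonyl butoxide and clonidine at 48 h. The time differences were 19 and 11 for nifedipine and tolbutamide, and the genotoxic contrast at 24 h gave 1612.

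With array weights the 24 h counts were 334, 1525, 11711, 96, 4240 and 2469 for 2-nitrofluorene, methapyrilene, piperonyl butoxide, clonidine, nifedipine and tolbutamide. At 48 h they were 660, 1, 3449, 817, 3282 and 1785 for 2-nitrofluorene, NNK, methapyrilene, clonidine, nifedipine and tolbutamide. Time differences were 5, 449, 1801, 20, 1080 and 57 for 2-nitrofluorene, methapyrilene, piperonyl butoxide, clonidine, nifedipine and tolbutamide. The genotoxic contrast gave 1642 and 4536, and the non-genotoxic carcinogen contrast gave 7833 at 24 h. The weights did not reach their convergence tolerance, so these counts are given as values only.

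Ranges follow for leaving out each replicate number in turn, which leaves 2 samples per compound group, or each low-spread array alone. At 24 h counts ranged from 21 to 86 for 2-nitrofluorene, 65 to 474 for methapyrilene and 3468 to 6573 for piperonyl butoxide. They ranged from 0 to 2 for clonidine, 491 to 2335 for nifedipine and 123 to 611 for tolbutamide. At 48 h the ranges were 24 to 117, 433 to 1433, 5145 to 12470, 16 to 125, 503 to 1571 and 192 to 637 in the same order. Time differences ranged from 2 to 27 for methapyrilene, 35 to 676 for piperonyl butoxide, 0 to 1 for clonidine, 0 to 19 for nifedipine and 0 to 11 for tolbutamide. The genotoxic contrast ranged from 300 to 1612 and 860 to 2351, the non-genotoxic carcinogen contrast from 1473 to 3637 and 2693 to 4665, and DMSO 48 h minus 24 h from 0 to 125.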

Other observations

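The tests of the solvent pattern and the counts of splits were set out before their values were seen, although the pattern itself was noticed in the data first.

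ENSG00000070669 rose in DMSO alone between 24 h and 48 h and rose at 24 h under 5 of the 7 compounds. Both rises were measured against the DMSO 24 h arrays. A hypothesis from these rises is that compounds bring forward a change that cultures undergo with time. The 24 h changes were set against the DMSO change from 24 h to 48 h, with different DMSO exposures in each so that no array was shared. The highest mean correlation across genes was 0.271, under methapyrilene, but it was 0.569 with 1 assignment of the exposures and -0.028 with the other. After a smooth dependence on level was removed it was 0.302. Without the 4 low-spread arrays the values were 0.425 for methapyrilene (0.439 and 0.410), 0.383 for tolbutamide, 0.258 for nifedipine and 0.255 for piperonyl butoxide. They were 0.081 for clonidine and -0.082 for NNK. For 2-nitrofluorene, under which ENSG00000070669 also rose, the value was 0.054, which goes against the hypothesis for that compound. After removing the level the value for methapyrilene was 0.432. Shared DMSO arrays and level-dependent spread therefore do not account for all of it in the 50 arrays. Genes are not independent replicates, and cell density, medium use and a stress common to both were not measured, so the hypothesis stays open.

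Other splits of the same arrays were counted. For each compound and time, the 3 compound and 6 DMSO arrays were split in all 84 ways. The real grouping is included in every count of splits or choices here and below. As many calls as the real split were found in 2 splits for 2-nitrofluorene at 24 h (65 real, 1050 highest other), 1 for methapyrilene (307, 6), 2 for piperonyl butoxide (5208, 5514), 3 for clonidine (1, 1), 1 for nifedipine (1641, 592) and 1 for tolbutamide (405, 9). At 48 h it was 1 split for 2-nitrofluorene (74, 0), methapyrilene (1002, 90), piperonyl butoxide (11780, 8681), clonidine (77, 1), nifedipine (1162, 299) and tolbutamide (441, 43). The share was under 0.05 in each of these, without correction across the comparisons. With all arrays, this argues against chance for the comparisons other than clonidine at 24 h. The splits were not repeated without the low-spread arrays. The clonidine share at 24 h rests on 1 called gene. That count was 0 without the replicate block, with DMSO exposure 1 alone and without replicate 2, so chance is not excluded there. For NNK the real count is 0, which all 84 splits reach by construction, so nothing was tested (highest other 10191 and 1). The 24 h splits with 1050, 5514 and 10191 calls each held DMSO 24 h exposure 2 replicate 2, and the last also NNK 24 h replicate 2, which points to the low-spread arrays as a structure of the samples. Among the 27 splits with 1 array of each replicate number, 1 of 27 reached the real count in each comparison other than those of NNK, with highest other counts of 0 for 2-nitrofluorene at 24 h and 3261 and 7634 for piperonyl butoxide.

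For the time differences 100 drawn splits were counted. As many calls were found in 4 for methapyrilene (18 real, 83 highest other), 4 for clonidine (1, 9), 3 for nifedipine (8, 128), 3 for tolbutamide (6, 407) and 8 for piperonyl butoxide (214, 6313). Most of these splits ignore the replicate number that the model blocks on. Among those with 1 array of each number at both times, 1 of 12 reached the count for methapyrilene, 1 of 10 for piperonyl butoxide, 1 of 17 for clonidine and 1 of 11 for nifedipine, each with 0 as the highest other. For tolbutamide it was 2 of 11, with a highest other of 8. These are too few for a share under 0.05, so no statement on chance is made for the time differences. For 2-nitrofluorene and NNK the real count is 0, which all 100 splits reach by construction (highest other 52 and 6778).

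For 2-nitrofluorene and NNK against the other compounds, 11 of 21 choices of 2 compounds gave as many genes at 24 h (1009 real, 9217 highest other) and 8 of 21 at 48 h (1767, 10213), so a chance choice of compounds cannot be excluded. The highest came from NNK with piperonyl butoxide and from piperonyl butoxide with nifedipine. For methapyrilene and piperonyl butoxide against the 3 others, the 10 choices are too few for a share under 0.05, with 4 at 24 h (2642 real, 3417 highest other) and 5 at 48 h (4076, 9541) as large. The 10 splits of 6 DMSO samples are likewise too few. The exposures gave 0 at both times, which all 10 splits reach by construction (highest other 1 and 0), and DMSO 48 h minus 24 h gave 5, reached by 1 split (highest other 0).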
